A study of Mus musculus with 8 samples.

How the data were processed

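Mouse mammary cells were compared by RNA immunoprecipitation sequencing (RIP-seq), in which RNA that comes down with an antibody is sequenced beside the RNA of the starting lysate. Per the labels, mammary glands of wild-type (WT) and Cpeb2 knockout (KO) mice were dissociated with enzymes, red cells were lysed, an epithelium-enriched fraction was taken without culture, and an antibody against CPEB2, a protein that binds the 3' untranslated region (3' UTR) of mRNAs, was used on both genotypes. The 8 libraries form 4 groups of 2, WT IP, WT Input, KO IP and KO Input, from RIP experiments 2 and 3 and cell preparations numbered 3 and 4 within each genotype. The labels do not state that the preparations came from different animals. The p-values of single rows therefore measure the spread between these libraries, which may be technical. Per the labels, poly(A) RNA was purified from Input samples only, and all libraries were made with a kit from New England Biolabs. An IP to Input difference therefore also contains the difference between selected and unselected RNA, and whether it is equal in both genotypes was not tested.

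One table of 20586 rows was used, each row being the 3' UTR of an Ensembl transcript with coordinates on the mouse build mm10. The submitters' processing notes name Bowtie 0.12.9, Bowtie2 2.2.2, DESeq2 with no version, and mm10, without roles or order. The counting rule, its use of strand and the handling of multiply mapped reads are not given in the sources used here. The deposited table holds 1 log2 value per group, which behaves as the log2 of a normalized count plus 1, since it is 0 where nothing was counted and its back-transformed mean was at or below the row's mean normalized count in every row. The mean normalized count over all libraries is a signal that the authors computed with DESeq2, per the file headers. The authors also deposited a log2 fold change with its standard error for the interaction, the log2 difference of IP and Input in WT minus that in KO. A positive value means a higher IP over Input in WT. This direction was read from a Spearman correlation across rows of 0.998 between that column and the same difference of the 4 group values. The deposited Wald score is the fold change divided by its standard error in every row. The deposited p-values are two-sided normal values of that score, and the authors' adjusted p is a Benjamini-Hochberg value over 5327 rows with a mean normalized count of at least 42.9. The remaining 11899 rows with a p-value have no adjusted p, and 3360 rows have no count.

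The table also holds 8 columns of values per library that are named by sequencing index alone. The labels do not pair these names with samples, so the columns were not used, and no column was assigned by its order or its values. Quasi-likelihood fits of counts per library had been planned as the main analysis, and none was run. The interaction is therefore the authors' own, with their standard error and p-value, at an adjusted p of 0.05, and the authors' threshold of 0.10 is an alternative. The other 4 comparisons are differences of the authors' group values with no error and no test, counted where they reach at least 1 on the log2 scale over the 5327 tested rows. Total counts per library were not used, so depth is unknown here and no interval that needs it is given. Precision is given by the authors' standard errors, which ranged from 0.305 to 1.49 with a median of 0.49, and 95% intervals are the estimate plus and minus 1.96 standard errors.

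The 21 gene lists, the tests and the rule for named genes were fixed before the data were examined. The 16 lists with at least 5 tested members were tested with limma 3.58.1 in R 4.3.3 (cameraPR on the Wald score, preset correlation 0.01), adjusted over the 16 lists. An estimated correlation and fry need values per library and were not run. The p-values of lists therefore measure spread over genes and not libraries. Each list's median was also set against 10000 random lists of the same size matched on mean count, or on mean count and 3' UTR length. The text names up to 12 genes per direction with the largest change past the threshold, filled by the smallest p where fewer passed, plus Cpeb1, Cpeb2, Cpeb3, Cpeb4, Tnfsf11, Tnfrsf11a, Pgr, Esr1 and Ccnd1, and up to 4 members per list by p. The rule's conditions on both RIP experiments and on average level need values per library and were replaced by the limit to tested rows. Gene models named Gm, Rik or LOC were passed over. For comparisons without a test, genes were ranked by the size of the difference. A few genes that these rules select are not reported here. Symbols are those of the file, of which 19543 of 19889 matched the reference table. A planned test of the cytoplasmic polyadenylation element was not run, because no genome sequence was used here. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used otherwise.

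The steps were tested on simulated data. For the interaction over 5327 rows with the authors' standard errors, 5% of 200 rows given a log2 change of 1 were recovered, 84% of 200 given 2 and 99.5% of 200 given 3, with 0, 9 and 7 false calls. A list whose Wald scores were shifted by 1.5 was called in 20 of 20 simulations, in which 1 other list was called. The simulated scores were independent standard normal values, without the shift and the trend over 3' UTR length of the real ones. They therefore test the steps and do not measure the rate of false calls in the deposited table. Alternatives tried were the threshold, the rows entering the adjustment, the zero point, the trend over 3' UTR length, the spread of the Wald score and overlapping rows. All except the threshold were chosen after seeing the data.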

Results

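The study asked which mRNAs associate with CPEB2 in mammary epithelial cells, per its title and design text. CPEB2 belongs to the cytoplasmic polyadenylation element binding proteins, which bind 3' UTRs and regulate poly(A) tails and translation. RNA recovered with an anti-CPEB2 antibody (IP) and RNA of the lysate (Input) were sequenced from WT and Cpeb2 KO cells, in 4 groups of 2 libraries. The KO immunoprecipitate is the design's control for recovery without CPEB2, whose absence was not checked here. Of 20586 3' UTR rows, 5327 had an adjusted p in the authors' deposited table, with a median mean normalized count of 103 and a highest of 4209. Depth per library is unknown here. All interaction values, standard errors (SE) and adjusted p-values below are from the authors' deposited table and its Wald test, and group values are the authors' log2 values.

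The knocked-out gene was examined first. The Cpeb2 row lies at chromosome 5, 43285947 to 43289724 (mm10), the 3' UTR of transcript ENSMUST00000114065. In the authors' deposited table its group values were 6.11 in WT Input and 5.98 in KO Input, a difference of 0.13. This 3' UTR row thus does not check the genotype labels, because the part of the gene that was deleted is not given in the sources used here. In the immunoprecipitates the authors' values were 9.64 in WT and 7.43 in KO. The Cpeb2 3' UTR was thus recovered above Input by 3.53 in WT and by 1.45 in KO, and its interaction in the authors' deposited table was 2.12 ± 0.45 (SE; Wald test, adjusted p = 0.00119), a 4.35-fold difference.

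The main comparison asked which 3' UTRs were recovered over Input more, or less, in WT than in KO. Transcripts of 120 rows were recovered more in WT and 0 less, at an adjusted p of 0.05 in the authors' deposited table (Wald test). The 120 rows are 2.25% of those tested, and their log2 interaction had a median of 1.74 and a highest value of 3.08. They include Cpeb2 itself, its paralogue Cpeb3, the cell cycle genes Ccnd1 and Cdk6, the Notch ligand Jag1, the Wnt receptor Fzd2, and the endothelial genes Flt1, Sox18 and Cdh5. The difference lay mostly in the immunoprecipitates. Over the 120 rows the authors' WT value exceeded the KO value by a median of 1.51 in IP, with all 120 above 0. In Input the median was -0.24, with 17 above 0. Over all tested rows these medians were 0.13 in IP and -0.09 in Input. The 120 rows were selected for an IP difference above their Input difference, so the sign in IP follows largely from the selection. At an unadjusted p under 0.05, 668 rows were higher and 58 lower in the authors' deposited table, and the smallest adjusted p of a row lower in WT was 0.109 (Wald test).

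The largest interaction belonged to Prkar2b, a regulatory subunit of protein kinase A, at chromosome 12, 31958476 to 31960388. Its authors' values were 8.71 in WT IP and 5.58 in KO IP beside 5.15 and 5.07 in the Inputs, and its interaction in the authors' deposited table was 3.08 ± 0.51 (SE; Wald test, adjusted p = 9.19e-06). Plxna2, a semaphorin receptor, had the next smallest adjusted p of the named genes in the authors' deposited table, with 2.60 ± 0.45 (Wald test, adjusted p = 1.65e-05). In the authors' deposited table the other genes with the largest interactions were Arhgap19, a GTPase-activating protein, with 2.96, Elovl4, an elongase of very long fatty acids, with 2.93, and Aqp7, a glycerol channel, with 2.93. They were followed there by Fzd2 with 2.93, Sostdc1, a secreted antagonist of BMP and Wnt signals, with 2.73, and the transcription factor Pou3f1 with 2.66. Kctd12b with 2.57, the zinc finger factor Prdm16 with 2.50, the protocadherin Pcdh17 with 2.46 and Cpeb3 with 2.39 completed the 12 in the authors' deposited table. Their standard errors there ran from 0.45 for Plxna2 to 0.78 for Sostdc1, so that the 95% intervals of these 12 overlap and their order is not resolved. With the median of all tested rows subtracted, Aqp7, Sostdc1 and Cpeb3 no longer passed the recomputed Wald test. With the trend over 3' UTR length subtracted, only Prkar2b, Elovl4, Fzd2, Pou3f1 and Plxna2 of the 12 passed it. Recovery above Input was not shared by all of the 12. The authors' values of Fzd2 (6.75 in WT IP and 6.83 in WT Input), Sostdc1 (5.30 and 6.04), Pou3f1 (6.74 and 7.09) and Pcdh17 (6.88 and 7.02) were lower in WT IP than in WT Input. The interaction of these 4 came with a deeper depletion in KO, where the authors' IP value lay 2.48 to 3.25 below Input. Over the 120 rows, 18 lay below Input in WT IP, and 50 lay above Input in WT and below it in KO.

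Ccnd1, a cyclin that drives entry into the cell cycle, is at chromosome 7, 144929931 to 144932606. Its authors' values were 9.69 in WT IP and 7.74 in KO IP against 9.19 and 9.11 in the Inputs, and its interaction in the authors' deposited table was 1.92 ± 0.43 (SE; Wald test, adjusted p = 0.00224). This interval overlaps the 3' UTR of Oraov1 on the opposite strand, named here after its values were seen, with 1.65 ± 0.46 in the authors' deposited table (Wald test, adjusted p = 0.0293). Because the use of strand in counting is not given in the sources used here, reads of the shared stretch are uncertain for both genes.

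No gene passed in the other direction. The 12 named genes with the smallest p there did not pass, with adjusted p-values from 0.109 to 0.275 in the authors' deposited table (Wald test). The gene with the smallest p, D8Ertd738e, had -1.62 ± 0.55 there, Ubb, which encodes ubiquitin, -1.63 ± 0.63, the glycolytic enzyme gene Tpi1 -1.05 ± 0.42 and the stress-response factor Atf3 -0.83 ± 0.33. Anxa6 had -1.32, the ribosomal protein gene Rpl27a -1.26, Serping1 -1.26, the ATP synthase subunit gene Atp5d -1.46 and Ghdc -2.32 in the authors' deposited table. The remaining 3 in that table were the myosin genes Myl9 with -1.20 and Myh14 with -1.37, whose interval overlaps another row on its strand, and the translation factor Eif5a with -0.83.

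The zero point and 3' UTR length each moved the count. The median log2 interaction of all tested rows was 0.23, 65.1% of rows were above 0 in the authors' deposited table, and with that median subtracted 30 rows passed, all higher in WT and all among the 120. With the trend over 3' UTR length subtracted, 17 of the 120 passed, and Cpeb2 (1.62, adjusted p = 0.0706) and Ccnd1 (1.55, adjusted p = 0.0657) no longer did under the recomputed Wald test. This trend is a running median of the interaction, so subtracting it also shifts the zero point. The median Wald score went from 0.47 to -0.003. The 17 calls therefore compare with the 30, and length alone was not subtracted.

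**Figure D1:**
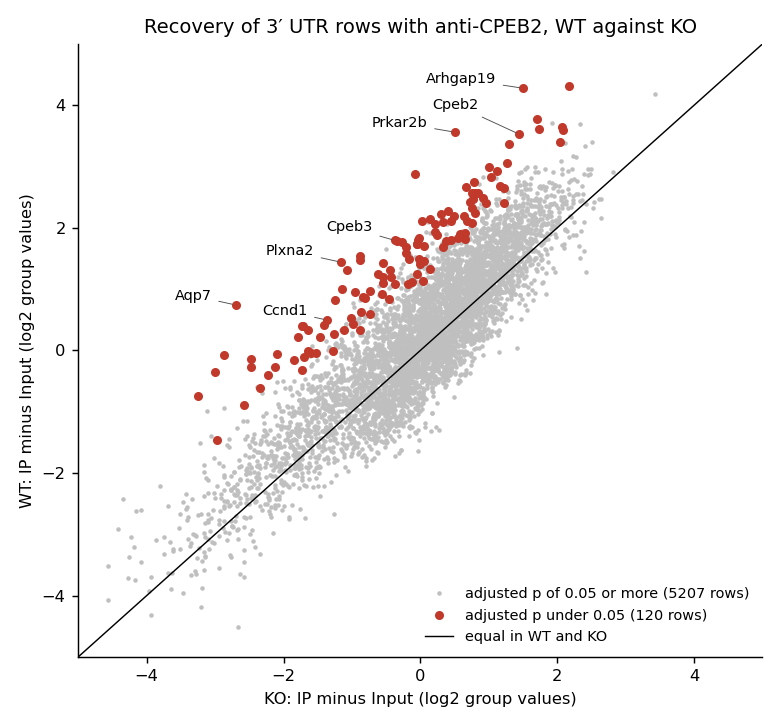
IP minus Input of the authors' log2 group values for each of the 5327 tested rows, KO on the horizontal and WT on the vertical axis, with the 120 rows past an adjusted p of 0.05 in red. All 120 lie above the line of equal recovery, which follows from their positive interaction. The Spearman correlation of both differences across rows was 0.864.

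**Figure D2:**
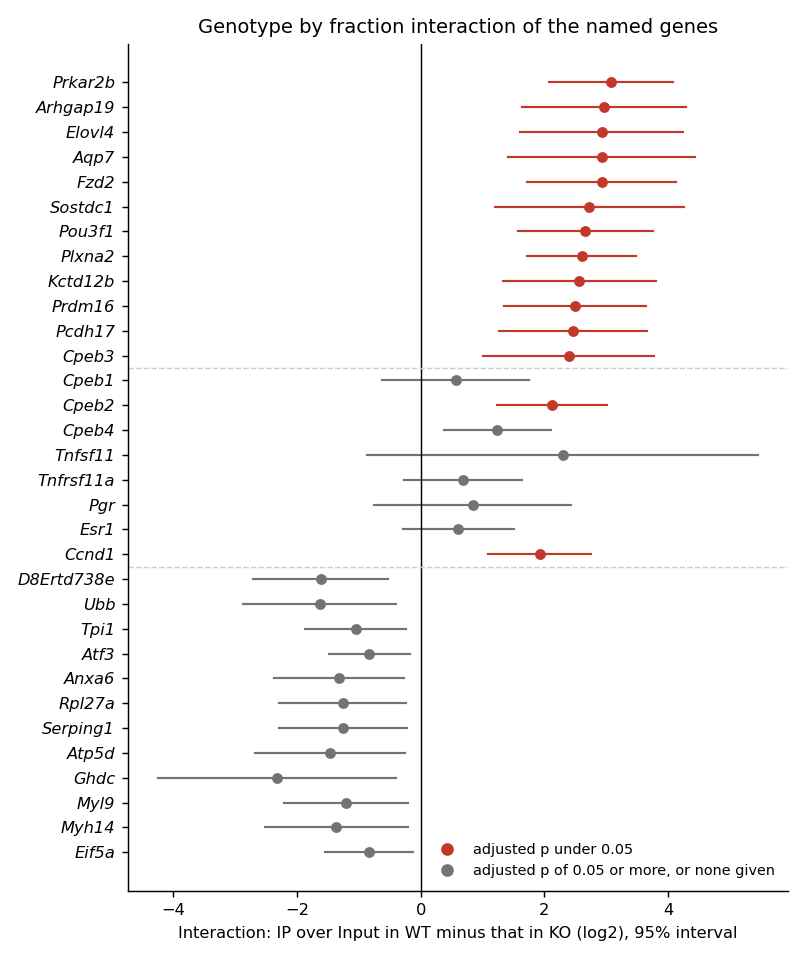
Interaction on the log2 scale with 95% intervals from the authors' deposited table, for the 12 largest past the threshold (top), the genes named in advance (middle) and the 12 with the smallest p in the other direction (bottom). Red marks an adjusted p under 0.05, and Prkar2b is highest with 3.08.

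Among the CPEB family all 4 members were measured, 2 rose (Cpeb2 and Cpeb3) and 2 did not pass, 3 passed when adjusted over the list alone, and the median was 1.68. For Cpeb3 the authors' deposited table gave 2.39 ± 0.71 (Wald test, adjusted p = 0.0377), for Cpeb4 1.24 ± 0.44 (Wald test, adjusted p = 0.127) and for Cpeb1 0.57 ± 0.60 (Wald test, adjusted p = 0.738). The authors' Input values of Cpeb3 (4.77 in WT and 5.54 in KO), Cpeb4 (6.43 and 7.07) and Cpeb1 (5.89 and 6.76) were all lower in WT. Part of the interaction of Cpeb3 and Cpeb4 thus lies in Input, and all of that of Cpeb1, whose IP value was also lower in WT. Cpeb3 no longer passed the recomputed Wald test with the median subtracted (2.16, adjusted p = 0.163), with the length trend subtracted (1.91, adjusted p = 0.290) or, at the same 2.39, with every row in the adjustment (adjusted p = 0.118). In IP the authors' WT value exceeded the KO value by 1.40 for Cpeb3, by 0.54 for Cpeb4 and by -0.36 for Cpeb1.

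Tnfsf11 encodes RANKL, the cytokine that the study's title names. Its row is at chromosome 14, 78277445 to 78278575, with a mean normalized count of 5.74, below the level at which the authors adjusted p. Its authors' values were 3.45 in WT IP, 1.55 in WT Input, 2.53 in KO IP and 2.54 in KO Input. The interaction in the authors' deposited table was 2.29 ± 1.61 (SE), with an unadjusted p of 0.155 and a 95% interval from -0.87 to 5.46, so neither a difference nor its absence was detectable at this depth. Pgr, the progesterone receptor gene, had 0.84 ± 0.81 in the authors' deposited table, with an unadjusted p of 0.299 and no adjusted p. Tnfrsf11a, which encodes the receptor RANK, had 0.69 ± 0.49 (Wald test, adjusted p = 0.584) and the oestrogen receptor gene Esr1 0.61 ± 0.46 (Wald test, adjusted p = 0.610) in the authors' deposited table. For Pgr and Esr1 the authors' WT value exceeded the KO value by only 0.01 in IP. Their positive interactions came from Input, where WT minus KO was -0.74 and -0.56. Of the 28 genes listed for RANK and progesterone signalling 19 were tested, 1 rose (Ccnd1) and 18 did not pass, with 2 adjusted over the list alone. The list's median was 0.33 (camera, adjusted p = 0.606), and the next members by p in the authors' deposited table were Cxcl12 with 1.07, Stat5b (Wald test, adjusted p = 0.211) and Rela with -0.71, none of which passed.

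Genes of polyadenylation and deadenylation stood above other rows. Of 19 tested, 1 rose (Tob2, a partner of the deadenylase complex) and 18 did not pass, with 4 adjusted over the list alone, and all 19 had an interaction above 0, 16 of them above the median of all rows. The list's median was 0.67 (camera, adjusted p = 0.00147). For Tob2 the authors' deposited table gave 1.22 ± 0.36 (Wald test, adjusted p = 0.0395), while Msi2 with 1.42, the cleavage factor gene Cpsf2 with 1.52 and Btg2 with 0.91 did not pass. Tob2 no longer passed the recomputed Wald test with the median subtracted (0.99, adjusted p = 0.243), with the length trend subtracted (0.85, adjusted p = 0.476) or, at the same 1.22, with every row in the adjustment (adjusted p = 0.124). Against random lists matched on mean count and 3' UTR length the list did not pass (adjusted p = 0.0676), and with the length trend subtracted it did (camera, adjusted p = 0.00556). Of 23 tested published targets of CPEB proteins, 2 rose (Cpeb2 and Cdk6) and 21 did not pass, with 3 adjusted over the list alone. Their median was 0.23, equal to that of all rows to 2 decimals (camera, adjusted p = 0.461). In the authors' deposited table Cdk6, a kinase partner of D-type cyclins, had 2.25 ± 0.68 (Wald test, adjusted p = 0.0429), while Cpeb4 with 1.24 and Tob1 with 1.16 did not pass. Cdk6 no longer passed the recomputed Wald test with the median subtracted (adjusted p = 0.170) or with the length trend subtracted (adjusted p = 0.271). With every row in the adjustment it did not pass either (adjusted p = 0.134).

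Wnt, Notch and Hedgehog genes also stood above other rows, with a median of 0.61 (camera, adjusted p = 0.00705). Of 18 tested, 2 rose and 16 did not pass, with 5 adjusted over the list alone. For Fzd2 the authors' deposited table gave 2.93 ± 0.61 (Wald test, adjusted p = 0.00101) and for Jag1 1.74 ± 0.45 (Wald test, adjusted p = 0.0148), while Nrarp with 1.54 and Wnt5a with 1.36 did not pass. Fzd2 also passed the recomputed Wald test with the median subtracted (adjusted p = 0.00757) and with the length trend subtracted (adjusted p = 0.0147), and Jag1 passed in neither. Against lists matched on mean count and length this list did not pass (adjusted p = 0.0676), and with the length trend subtracted it did (camera, adjusted p = 0.00799). Of 20 junction genes tested 0 rose, with a median of 0.25 (camera, adjusted p = 0.969), and among the members with the smallest p in the authors' deposited table were Tjp1 with 0.94, Ctnnd1 with 0.72 and Cldn1 with 0.62.

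Among markers of cell types, endothelial genes were higher and basal genes lower than other rows. Of 13 endothelial markers tested, 3 rose and 10 did not pass, with 5 adjusted over the list alone, 10 above 0 and a median of 0.86 (camera, adjusted p = 0.00256). In the authors' deposited table the vascular growth factor receptor gene Flt1 had 1.49 ± 0.37 (Wald test, adjusted p = 0.00861), the transcription factor Sox18 2.14 ± 0.62 and the cadherin gene Cdh5 1.32 ± 0.38 (Wald test, adjusted p = 0.0347 for both), while Kdr with 1.24 did not pass. With the median subtracted none of Flt1 (1.26, adjusted p = 0.0816), Sox18 (1.91, adjusted p = 0.163) and Cdh5 (1.09, adjusted p = 0.210) passed the recomputed Wald test. With the length trend subtracted Sox18 passed it (2.51, adjusted p = 0.0228), and Flt1 (0.98, adjusted p = 0.317) and Cdh5 (1.11, adjusted p = 0.231) did not. Of 19 basal and myoepithelial markers tested 0 passed in either direction, 2 were above 0 and the median was -0.47 (camera, adjusted p = 6.3e-05). In the authors' deposited table Myl9 had -1.20, Postn -0.79, Mylk 0.69 and Krt5 0.87. These 2 lists also passed against random lists matched on mean count and 3' UTR length (adjusted p = 0.0128 for each). Both tests take their spread over genes and not libraries. Markers that vary together between libraries would make such p-values too small, and this was not tested. The median authors' Input difference of WT minus KO was 0.06 over 17 endothelial and 0.18 over 25 basal markers with a mean count of at least 10.

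Fibroblast and hormone-receptor-positive luminal markers were lower than other rows by the list test, and luminal progenitor markers did not differ from them in it. Of 18 fibroblast markers 0 passed and the median was -0.27 (camera, adjusted p = 0.000344), with Gsn at -0.70, Col3a1 at -0.69, Fn1 at -0.50 and Dpt at -0.48 in the authors' deposited table. Of 13 hormone-receptor-positive markers 0 passed and the median was -0.25 (camera, adjusted p = 0.0198), with Ly6d at -0.80, Krt8 at -0.69, Krt18 at -0.83 and S100a6 at -0.77 in the authors' deposited table. Neither list passed against lists matched on mean count and length (adjusted p = 0.0676 for each), and with the length trend subtracted the fibroblast list passed (camera, adjusted p = 0.0122) and the other did not (camera, adjusted p = 0.205). Of 17 luminal progenitor markers 0 passed over all rows and 1, the receptor gene Kit, did when adjusted over the list alone. The median was 0.24 (camera, adjusted p = 0.606, direction lower than other rows), with Kit at 1.31, Ehf at 0.87, Lipa at 0.93 and Lcn2 at -0.93 in the authors' deposited table. Of 6 adipocyte markers 1 rose (Aqp7) and 5 did not pass, with 1 adjusted over the list alone, and the median was 0.28 (camera, adjusted p = 0.525), with Scd1 at 0.61, Car3 at 0.73 and Fabp4 at -0.29 in the authors' deposited table. Of immune markers 2 were tested and did not pass, Cd74 with -1.19 and Laptm5 with -0.40 in the authors' deposited table.

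The tested ribosomal protein and oxidative phosphorylation genes, many with short 3' UTRs, were lower than other rows. Only 18 of 78 listed ribosomal protein genes and 7 of 38 listed oxidative phosphorylation genes had the counts to be tested. Of 18 ribosomal protein genes 0 passed, 3 were above 0 and the median was -0.51 (camera, adjusted p = 0.000344), with Rpl27a at -1.26, Rpl41 at -0.83, Rplp0 at -0.90 and Rps9 at -0.60 in the authors' deposited table. Of 7 oxidative phosphorylation genes 0 passed and the median was -0.83 (camera, adjusted p = 0.00238), with Uqcrh at -1.41, Uqcr10 at -1.10, Cox8a at -0.83 and Cox6b1 at -0.91 in the authors' deposited table. Their median 3' UTR lengths were 617 and 201 bases against 1818 over all tested rows, and neither list passed against lists matched on mean count and length (adjusted p = 0.0512 and 0.0676). Of 18 unfolded protein response genes 0 passed and the median was -0.10 (camera, adjusted p = 0.0198; matched lists, adjusted p = 0.447), with Hsp90b1 at -0.83, Calr at -0.72, Edem1 at 0.70 and Pdia6 at -0.68 in the authors' deposited table. Of 29 immediate early and stress genes 0 passed, with a median of -0.02, a mean of 0.04 and a list test that did not pass (camera, adjusted p = 0.0822, direction lower). The list was lower than random lists matched on mean count (adjusted p = 0.00192) but not than those also matched on length (adjusted p = 0.547). For Btg2 the authors' deposited table gave 0.91, for Atf3 -0.83, for Egr2 1.22 and for Hspa1b -0.73. Of 19 NF-kB targets 0 passed and the median was 0.10 (camera, adjusted p = 0.525, direction lower), with Bcl3 at 1.08, Nfkbie at -0.80, Sod2 at 0.73 and Lif at 0.52 in the authors' deposited table. Of the replication-dependent histone genes 2 were tested and did not pass, Hist1h1c with -0.24 and Hist3h2a with -0.31 in the authors' deposited table. The cell cycle and erythroid lists had 0 tested members.

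**Figure D3:**
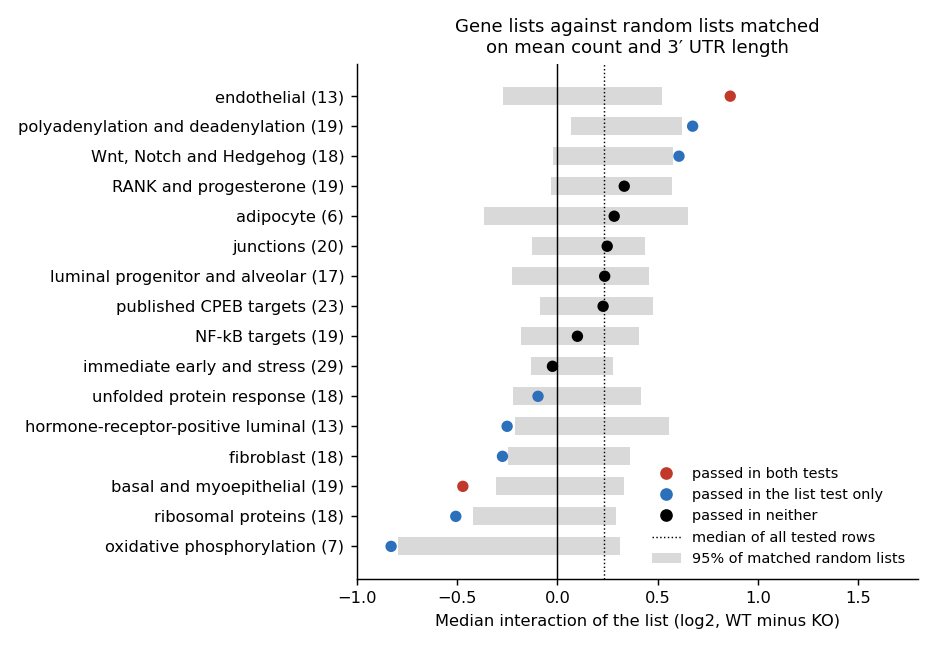
Median log2 interaction of each of the 16 lists (points, with the number of tested members) and the central 95% of medians of random lists matched on mean count and 3' UTR length (bars). The endothelial list at 0.86 and the basal list at -0.47 passed both tests.

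The interaction was larger in rows with longer 3' UTRs. From the shortest to the longest quintile of tested rows the median interaction was -0.23, 0.12, 0.22, 0.40 and 0.52, and 6, 17, 23, 30 and 44 rows were called. The Spearman correlation of length and interaction was 0.391 across rows, which are not independent replicates. Length also went with the authors' IP difference of WT and KO (correlation 0.296), with their Input difference in the opposite direction (correlation -0.306), and with IP over Input within WT (0.370) and within KO (0.221).

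**Figure D4:**
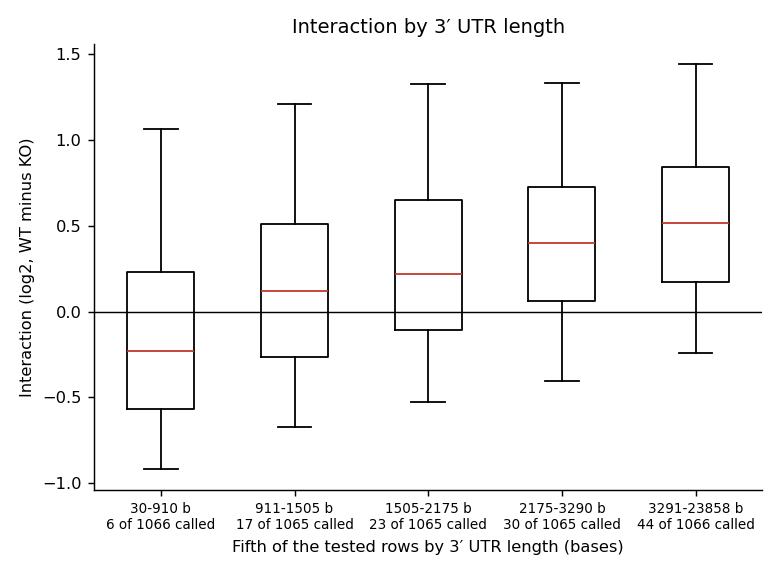
Log2 interaction of the authors' deposited table in quintiles of the tested rows by 3' UTR length, with medians in red, boxes from the lower to the upper quartile and whiskers over the central 90% of rows. The medians run from -0.23 in the shortest to 0.52 in the longest quintile.

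The direct comparison of immunoprecipitates, WT against KO, asked the same without Input. The authors' value was at least 1 higher in WT IP for 361 rows and at least 1 lower for 45, or 251 and 84 with the median difference subtracted, with no test. The difference was 3.32 for Aqp7, 3.22 for Elovl4, 3.14 for Prkar2b and 2.40 for Fzd2, and the forkhead factor Foxq1, with 5.70 in WT IP and 2.71 in KO IP, lay between these. Gcnt1 (2.29), Pou3f1 (2.23), Sox18 (2.22), Cpeb2 (2.21), Cdk6 (2.21), Sostdc1 (2.17) and the planar polarity gene Vangl2 (2.15) followed. At the other end, the WT IP value differed by -2.21 for Ghdc, -1.60 for Fam193a, -1.59 for Dmbt1, -1.59 for the oestrogen-responsive gene Greb1 and -1.54 for Cd74, the invariant chain of antigen-presenting cells. Padi2 (-1.41), Mad2l1 (-1.38), Myh14 (-1.35), Cyp1a1 (-1.34), Uqcrh (-1.33), Ptpn5 (-1.33) and D8Ertd738e (-1.31) completed the 12. The value of Ghdc in WT IP was only 1.64, so its difference rests on few counts. Foxq1 was also higher in WT Input, by 0.87, and its interaction of 2.52 ± 0.94 in the authors' deposited table did not pass (Wald test, adjusted p = 0.154).

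The Inputs compared RNA abundance between genotypes and differed less across rows than the immunoprecipitates did. The SD across tested rows of the authors' WT minus KO difference was 0.25 in Input and 0.55 in IP. No row was at least 1 higher in WT Input and 10 were at least 1 lower, or 3 and 5 with the median difference subtracted, and these differences have no test. The lowest were Syn2 (-1.75), Padi2 (-1.16), Slc15a2 (-1.11), the B-cell complement receptor gene Cr2 (-1.10), the lymphocyte factor Runx3 (-1.08) and Mboat2 (-1.08). Mettl7a1 (-1.05), the phagocyte oxidase gene Cybb (-1.04), Zfp9 (-1.03), Greb1 (-0.99), Atg5 (-0.98) and Rapgefl1 (-0.97) followed. The highest were Slc25a10 (0.98), Ccdc141 (0.98), Ogfrl1 (0.94), Foxq1 (0.87), Tspan2 (0.83), Atp5d (0.81) and Cd14 (0.80), then Slc7a8 (0.77), Fbn2 (0.74), Frmd8 (0.73), Pald1 (0.71) and Pdrg1 (0.70). Immune markers were lower in WT Input by the authors' values, with a median difference of -0.54 and 1 of 9 higher in WT. The median was -0.17 for fibroblast (4 of 20 higher in WT) and -0.15 for hormone-receptor-positive markers (2 of 17). It was 0.16 for luminal progenitor (12 of 20) and -0.08 for adipocyte markers (3 of 9), beside -0.09 over all tested rows. Whether cell content differed between the preparations was not tested for these lists.

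Recovery over Input was ranked similarly in both genotypes. In WT the authors' IP value was at least 1 above Input for 1499 rows and at least 1 below for 836, and in KO for 906 and 905. These differences have no test and contain the poly(A) selection of Input. The largest in WT were Gcnt1 (4.31), Arhgap19 (4.28), Prrg1 (4.18), St8sia4 (3.77), Plscr4 (3.72), Alg10b (3.70) and the decapping factor gene Dcp1a (3.65). Plekhg1 (3.62), the thrombin receptor gene F2r (3.60), Prkar2b (3.56), Cpeb2 (3.53) and Gtf2a1 (3.40) completed the 12. In KO the same difference was 2.18 for Gcnt1, 3.42 for Prrg1, 1.70 for St8sia4, 1.92 for Plscr4, 2.33 for Alg10b and 2.07 for Dcp1a. It was 1.74 for Plekhg1, 2.09 for F2r, 0.50 for Prkar2b, 1.45 for Cpeb2 and 2.50 for Gtf2a1, and Arhgap19 had 5.28 in KO IP and 3.78 in KO Input. Prrg1 was also the highest in KO, and others among the highest there were Nova1 (2.64), Mospd2 (2.64), the lysosomal gene Lamp2 (2.61) and Ankrd28 (2.53). Crebzf (2.52), Gtf2a1 (2.50), Pkia (2.48), Phip (2.45), Prex2 (2.45) and Abca5 (2.43) followed. The lowest in WT were Ghdc (-4.51), Espn (-4.31), Ecd (-4.18), Tenm2 (-4.08), Dnase2a (-3.96), Celf4 (-3.93) and Dusp23 (-3.89), then Psd (-3.87), Tnpo3 (-3.75), Il17re (-3.71), Zfp617 (-3.70) and Ccdc86 (-3.69). Several of these rest on few counts, with WT IP at 1.64 for Ghdc, 2.35 for Dusp23, 2.52 for Espn and 2.82 for Ecd. Among the highest, Prrg1 had Input values of only 2.85 in WT and 2.70 in KO. Among the lowest in KO were Tenm2 (-4.56), Frrs1 (-4.41), Borcs7 (-4.35), Il17re (-4.27), Rtn1 (-4.26) and Bmp8a (-4.23), then Mettl1 (-4.19), Tnpo3 (-4.17), Ncmap (-4.15), Lias (-4.09) and Syt11 (-4.08). Several of the lowest in KO also rest on few counts, with KO IP at 2.60 for Ncmap, 2.63 for Bmp8a, 2.71 for Borcs7 and 2.87 for Il17re. The Spearman correlation of the WT and KO differences across rows was 0.864, and the 2 differences share no library.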

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

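The tests of the Wald score's spread, of the missing calls lower in WT, of Input alone and of endothelial cell number were chosen only after the results were seen. The interaction tests a difference between genotypes directly, and 120 rows passed it in the authors' deposited table. Of the genes named for the interaction, those past the threshold there were Prkar2b (3.08), Arhgap19 (2.96), Elovl4 (2.93), Aqp7 (2.93), Fzd2 (2.93), Sostdc1 (2.73), Pou3f1 (2.66), Plxna2 (2.60), Kctd12b (2.57), Prdm16 (2.50), Pcdh17 (2.46) and Cpeb3 (2.39). Cdk6 (2.25), Sox18 (2.14), Cpeb2 (2.12), Ccnd1 (1.92), Jag1 (1.74), Flt1 (1.49), Cdh5 (1.32) and Tob2 (1.22) also passed there.

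All 120 rows were higher in WT, which is what recovery by an antibody whose target is absent from KO cells would give. For an understated spread, the first test centred and scaled the Wald scores, and 2 calls were left, which met the criterion set for that explanation. After that outcome was seen the test was replaced, because the spread it scaled by carries the trend over 3' UTR length. That spread was 1.22, the SD implied by the distance of the lower quartile of the scores from their median. With the length trend subtracted this SD was 1.04, which argues against this explanation. The order of these choices makes that weak, and the measure does not cover the tail of the scores. The criterion for the authors' scaling was written before its outcome was seen, although subtracting the median was itself chosen after seeing the data. That test came out for the scaling, as 30 of the 120 rows were left, under 50%, once the median of 0.23 was subtracted. In a criterion written after this was seen, calls in the other direction stayed at 0, with 333 rows higher and 182 lower at an unadjusted p under 0.05, so the zero point was not shown to account for their absence. Whether the median itself is technical or reflects weak recovery of many mRNAs cannot be decided without counts per library or spiked RNA.

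The interaction was larger with longer 3' UTRs. Read depth was argued against, because within deciles of mean count the correlation of length and interaction had a median of 0.359 and ran from 0.310 to 0.410. A difference between the Inputs alone was argued against by a correlation of 0.296 between length and the difference of the immunoprecipitates. RNA integrity, GC content and the number of binding sites per 3' UTR stay open and were not tested.

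The endothelial list was higher in WT. The lengths and levels of its genes were argued against, as its median lay at percentile 99.93 of matched random lists. For more endothelial cells in the WT preparations, the median Input difference of the 13 tested markers was 0.06 with an upper bootstrap bound of 0.143, below the 0.398 that is 50% of their median IP difference. The highest Input difference of any of 17 markers was 0.374, which argues against this explanation for the IP difference. In the interaction, which subtracts Input, more cells raising IP and Input alike would cancel, so there this check decides little. The bootstrap interval of the IP difference ran from 0.22 to 1.05, and both intervals are over genes and not libraries. The basal list passed the same tests in the opposite direction, with a median of -0.47, so a shifted list alone does not point to binding. A candidate explanation for the endothelial list is that CPEB2 binds these mRNAs in endothelial cells left in the epithelium-enriched fraction. This is a hypothesis, found on the data it describes, which immunoprecipitation from sorted endothelial and epithelial cells of both genotypes would decide, and GC content and single libraries were not tested for this list.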

How the results depend on the processing

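All alternatives here except the threshold of 0.10 were chosen after seeing the data. No paired analysis was possible here because the columns per library carry only sequencing indexes, so neither RIP experiment nor cell preparation could enter a new fit. Whether the authors' own fit held either of them is not given in the sources used here. For the same reason the planned normalizations, count filters, other tools, robust dispersion, replicate blocks, leaving out each library, fits of 4 libraries, removal of the 50 most abundant genes, estimated correlation and fry were not run, and rows were not summed because each symbol has 1 row. The motif alternatives were not run either. The number of rows higher in WT went from 120 to 169 at an adjusted p of 0.10. It was 109 over rows with a mean count of at least 100, of which 93 were among the 120. With 1 row per overlapping set it was 119, of which 118 were among the 120. When every row with a p-value entered the adjustment it was 47, since more rows were tested, and 45 of these were among the 120. It was 30 with the median subtracted, 17 with the length trend subtracted, which also shifts the zero point, and 2 with Wald scores centred and scaled. In every setting 0 rows were lower in WT. Of the 20 genes named for the interaction that passed, 13, 11, 6 and 2 passed in the last 4 settings, with all directions kept. Flt1 went from 1.49 ± 0.37 to 1.26 with the median and 0.98 with the length trend subtracted, while Aqp7 lost its call at an unchanged 2.93 when every row entered (adjusted p = 0.0519), so calls ended with smaller and with equal changes. Cpeb2 had 1.89 with the median subtracted (adjusted p = 0.0148), 1.62 with the length trend subtracted (adjusted p = 0.0706) and 1.91 after centring and scaling (adjusted p = 0.238). Against lists matched on mean count 8 lists were called, where the polyadenylation and Wnt lists dropped out of the 9 of camera and the immediate early list came in. When also matched on length 2 were called, and 5 by camera with the length trend subtracted. At a mean count of at least 100, and then at least 10, the rows at least 1 higher and lower were 182 and 7, then 754 and 315, for WT IP against KO IP, and 0 and 1, then 37 and 54, for the Inputs. For WT IP against Input they were 891 and 388, then 2206 and 2063, and for KO 537 and 520, then 1411 and 1870. The cause of these moves was not tested. With the median difference subtracted, 251 rows were at least 1 higher and 84 lower in WT IP than in KO IP, and 3 were higher and 5 lower in Input. The correlation with the group values was 0.999 at the higher level. From the lowest to the highest quintile by mean count the median standard error went from 0.60 to 0.39, the median change from 0.08 to 0.35 and the calls from 6 to 48.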

Other observations

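Recovery over Input also differed between gene groups within each genotype, as values with no test. By the authors' group values the median of IP minus Input was -2.96 in WT and -2.40 in KO for 4 erythroid genes with a mean count of at least 10, among them the globin genes Hba-a1, Hba-a2 and Hbb-bs. It was -1.01 and -0.43 for 11 cell cycle genes, and -1.04 and -0.37 for 9 immune genes. Immediate early and stress genes lay above Input alike, with 0.48 in WT and 0.47 in KO over 29 tested members. For 7 replication-dependent histone genes, whose mRNAs mostly lack a poly(A) tail, it was -0.02 in WT and 0.29 in KO. Median differences of WT and KO Input were -0.44 for the erythroid, -0.10 for the cell cycle and -0.19 for the histone genes.

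The 3' UTRs of Cpeb2 and Cpeb4 were above Input in KO as well, by 1.45 and 1.40 in the authors' group values, beside 3.53 and 2.58 in WT. Cpeb3 and Cpeb1 lay below Input in KO, by -0.37 and -1.28.

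The strain label names C57BL/6J and 129, so DNA of one strain kept around the deleted locus was tested as a source of Input differences near Cpeb2, in a test chosen after the Cpeb2 values were seen. The median absolute Input difference of the 29 tested rows within 10 Mb was 0.22, against 0.17 for random sets matched on mean count and at percentile 88.45 of them, and 0 of these rows were called in the interaction. The difference was above the random median without reaching the level set for this test, so such an effect is neither shown nor excluded.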
